A study of Mus musculus with 2 samples.

How the data were processed

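The series measured DNase I accessibility in stomach tissue of B6NCrl mice on postnatal day 0, in 1 group of 2 biological replicates with 1 library each. Per the labels both libraries carry the same donor, the sex of the animals was not collected, and the sequencing of replicate 2 names a pair of instruments while that of replicate 1 names none. Both replicates were used throughout.

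For each replicate a list of peaks and a list of hotspots on build mm10 was used. Per the deposited file lists each was called from that replicate's own filtered alignments. Peaks are at most 150 bp wide, and their signal, as deposited, is a whole number from 2 or 3 up to 150, with no unit and no scaling by depth stated. It was used only to rank or filter peaks within a list. The hotspots carry the -log10 of a q value, by the layout of the deposited files, from 1.30 to 100, and 38.9 and 39.4% of the hotspots sat at 100. Their score, a display value in the deposited files that follows the q value, was used in no result. The aligner, the peak caller and its thresholds are not given in the sources used here. The number of reads per library is not given either, so the depth is unknown, and depth limits which weak sites could be called. No interval reached beyond a chromosome end of mm10. Peaks on the mitochondrial chromosome and on scaffolds were left out, which kept 139374 and 152779 peaks on the 19 autosomes, X and Y.

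The gene lists, the motifs, the tests, the rule for named genes, the first set of alternatives and 5 predictions were fixed before the data were examined. Random lists matched on promoter CpG content and the mean in place of the median were added after seeing the data.

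Peaks of both replicates that overlapped by at least 1 bp were joined into shared regions (bedtools 2.31.1), and 96.6% of these were made of 2 peaks. Chance overlap came from 20 shifts of a list within chromosomes. Genes and transcripts were those of GENCODE M21, with 21911 protein-coding genes after 27 repeated symbols were dropped. The centre of a region was assigned to promoter (within 1 kb of a transcription start), exon, intron or intergenic, in that order. A promoter counted as open when a shared region overlapped the 1 kb on either side of any of the gene's starts. Because the same region must be found in both replicates, a list's share can lie below its share in each replicate alone. A gene without an open promoter by this rule can still have a promoter peak in a single replicate. A locus was the gene body with 10 kb on either side.

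There were 25 gene lists: gastric epithelial transcription factors, gastric glandular products, forestomach squamous epithelium, general epithelium, intestinal epithelium, enteroendocrine cells, visceral smooth muscle, interstitial cells of Cajal, gut mesenchyme and fibroblasts, foregut patterning signals, enteric neurons and glia, endothelium, immune cells, erythroid cells, mesothelium, hepatocytes, exocrine and endocrine pancreas, cardiac and skeletal muscle, brain neurons and glia, germ cells, photoreceptors, Hox paralogue groups 1 to 5, 6 to 8 and 9 to 13, and housekeeping. The symbols Cblif, Loricrin and Amy2b had no match in the annotation, and the older symbols Gif and Lor of the first pair did. Krt19 and Hoxb5 each stand in 2 lists. Promoters of a list were compared with those of all other protein-coding genes by Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment over the 25 lists and a threshold of 0.05. The median number of shared regions per locus was placed among 10000 random lists of the same size, matched on locus length in 20 bins, and called when its percentile was in the highest or lowest 2.5%. Random lists tied with the list were ranked at their middle, so a list on the limit of the central 95% can be called. These percentiles, and those of promoters against lists matched on CpG content, were not adjusted for the 25 lists, so some calls can arise by chance. These tests are across genes, which are not independent replicates, and describe these 2 libraries only.

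Each of 38 consensus sequences was searched on both strands of the shared regions and of windows of equal width 1 kb away that overlapped no peak. Odds ratios have 0.5 added to each count and 95% intervals. Matches were tested by Fisher's exact test with Benjamini-Hochberg adjustment over the 38. A motif was called when it passed and its interval lay above that of the same string read backwards. The GC box GGGGCGGGG reads the same backwards, so it had no usable control, and the reversed strings of NRF1, YY1 and RFX had few matches. An AP-1 match and the reversed AP-1 string can overlap where the flanking bases fit, and how far this moves that control was not measured. Very small p-values that the computer stores as 0 are not printed.

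Named genes followed a rule. It took the 3 members of each list with the most shared regions in the locus, up to 2 members without an open promoter, the 10 genes outside the lists with the most regions, the 10 regions with the highest mean signal rank, and the 10 genes with the largest difference between replicates. Other list members are named as examples, chosen after their values were seen. Where few members were open, all are named. Some items that the rule takes are not reported here.

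The alternatives were an overlap of at least 50% of each peak, only the stronger 50% of each replicate's peaks, lists of equal length, hotspots in place of peaks, promoter windows of 250 bp and 2.5 kb, protein-coding transcripts only, a background without chemoreceptor genes, gene bodies alone or with 50 kb on either side, promoter regions left out, random lists matched also on open promoters, motif windows of 100 and 300 bp, background windows 1 to 10 kb away matched on GC content, and each replicate alone.

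The steps were tested on simulated data. Of 3000 shared regions made, 3000 were found. Over 1000 simulated promoter lists among 21911 genes, 90% of lists made lower and 63.8% of lists made higher were called, and 0.75% of lists without an effect. Over 200 simulated locus lists, 97.5% of those with doubled rates were called and 3.75% of those without an effect. A planted HNF4 site was found in 10.3% of windows, with 10.2% predicted, and its reversed string had an odds ratio of 0.789. AP-1 had been planted first and was replaced because its reversed string was raised too.

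Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, samtools 1.23.1 and matplotlib 3.10.9.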

Results

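Open chromatin of the newborn mouse stomach was mapped by DNase-seq, in which the enzyme DNase I cleaves DNA where it is accessible and the released fragment ends are sequenced. The tissue came from B6NCrl mice on postnatal day 0. The series holds 1 group of 2 biological replicates, each a single library, so no groups can be compared. The labels give both libraries the same donor, and they do not state whether separate animals or pools were used. Replicate 1 had 139654 peaks and replicate 2 had 153178, covering 20.9 and 23.0 Mb of the mouse genome (build mm10). Hotspots, the wider regions of raised cleavage, numbered 128468 and 138836 and covered 38.1 and 42.5 Mb. The number of reads behind each list is unknown here, and intervals given with shares cover counting error only. The peak signal has no stated scale and served only to rank peaks within a list. Its median was 44 in replicate 1 and 52 in replicate 2.

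Most accessible sites of the newborn stomach were found in both libraries. Peaks that overlapped between replicates formed 105606 shared regions with a median width of 170 bp, together 18.5 Mb or 0.677% of the genome. In replicate 1, 77.6% of peaks on the autosomes, X and Y had a partner in replicate 2 (95% Wilson interval 77.4 to 77.8). In replicate 2 the share was 70.7% (70.5 to 71.0). Both are the same overlap divided by lists of different length, so their difference is no measure of replicate spread, and with lists of equal length they were 74.3 and 74.0%. Shifting 1 list along the chromosomes left a mean overlap of 1.75%, with a range of 1.64 to 1.88% over 20 shifts. Signal ranks across the shared regions were correlated with a Spearman coefficient of 0.910, a description across regions, which are not independent replicates. Sharing followed signal. Among the weakest 10% of peaks 24.8% in replicate 1 and 36.2% in replicate 2 were shared, and among the strongest 10% the shares were 99.6 and 99.4%. Hotspots overlapped to a similar extent, with 79.3% of those in replicate 1 and 72.3% of those in replicate 2 shared.

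**Figure D1:**
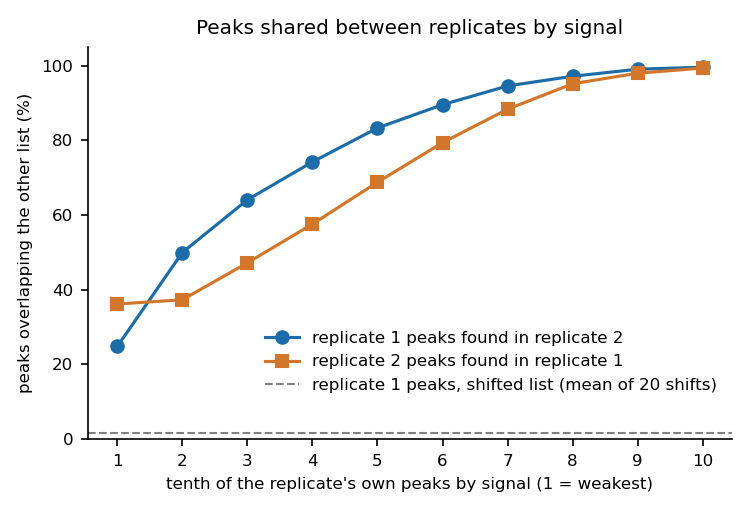
Percent of each replicate's peaks that overlap a peak of the other replicate (vertical axis), by groups of 10% of the peaks ranked by signal from weakest to strongest (horizontal axis), with 1 line per replicate and a dashed line for lists shifted along the chromosomes. Sharing climbs from 24.8 and 36.2% in the weakest group to 99.6 and 99.4% in the strongest.

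The strongest shared regions lay mostly at promoters. The region with the highest mean signal rank was at the promoter of Hjurp, a histone chaperone of centromeres (mm10 chromosome 1, 88277556 to 88277725), with a signal of 147 in replicate 1 and 146 in replicate 2. It was followed by an intronic region of Aida (chromosome 1, 183299236 to 183299385; 144 and 149). The promoter of Sp1, a transcription factor that binds GC-rich promoters, came next (chromosome 15, 102405876 to 102406025; 133 and 138). Others of the 10 strongest lay at promoters of Rnf31, Map3k3, Derl2, Calr, Gm45885 and Hdgfl2. Of all shared regions, 31.5% had their centre within 1 kb of an annotated transcription start (95% Wilson interval 31.3 to 31.8), against 5.89% of 200000 random positions. Exons held 3.64%, introns 35.8% and intergenic sequence 29.1%, against 3.08, 37.2 and 53.9% of random positions. Median signal at promoters was 62 in replicate 1 and 74 in replicate 2, and at intergenic regions 46 and 58. With a promoter window of 250 bp the promoter share was 18.6%.

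Genes of the gastric epithelium had open promoters in both libraries. A shared region lay within 1 kb of a transcription start at 20 of 21 gastric epithelial transcription factors, against 66.4% of all 21911 protein-coding genes. Among them were Sox2, Gata4, Gata6, Foxa1, Foxa2, Hnf4a and Klf5. Foxq1 was the exception, with a promoter peak in replicate 2 only. Of 26 products of the gastric glands 24 had one, including the trefoil factors Tff1 and Tff2, the gastrokines Gkn1, Gkn2 and Gkn3, the proton pump subunits Atp4a and Atp4b of parietal cells, and intrinsic factor (Gif). Of the others, Aqp5 had a promoter peak in replicate 2 only and Chia1 in neither replicate. All 20 genes of the general epithelium list, among them the adhesion molecules Epcam and Cdh1 and the keratins Krt8, Krt18 and Krt19, had one, as did all 25 housekeeping genes. These 4 lists were above the other protein-coding genes by Fisher's exact test, two-sided, with Benjamini-Hochberg (BH) adjusted p of 0.0114 for the transcription factors, 0.0101 for the glandular products, 0.00230 for general epithelium and 6.67e-04 for housekeeping. The transcription factors reached 95.2% in replicate 1 and 100% in replicate 2, and the glandular products 92.3 and 96.2%. With only the stronger 50% of each replicate's peaks the share of glandular products was 76.9% and no longer past the threshold.

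The lists of other stomach and gut cell types were not set apart from other genes by the test. All 8 genes of interstitial cells of Cajal, the pacemaker cells of gut motility, had a shared promoter region, among them Kit, Ano1 and Etv1 (adjusted p = 0.104, BH, Fisher's exact test). Visceral smooth muscle had 16 of 22 (0.711), including the contractile genes Myh11, Actg2, Cnn1 and Tagln. Acta2 had a promoter peak in replicate 2 only, and Myocd in replicate 1 only. In replicate 2 alone the smooth muscle list was above other genes at 95.5%. Foregut patterning signals had 19 of 22 (0.113), including the Hedgehog receptor Ptch1 with Bmp4, Fgf9 and Fgf10, while Shh had a promoter peak in replicate 2 only. That list passed the threshold in each replicate alone, at 90.9% in replicate 1 and 95.5% in replicate 2, and with a 2.5 kb promoter window, also at 95.5%, but stood at percentile 46.1 of random lists matched on promoter CpG content. Gut mesenchyme and fibroblasts had 14 of 25 (0.365), with Foxf1, Gli1 and Col1a1 among them. Barx1 had a promoter peak in replicate 1 only, and Nkx3-2 in neither replicate. Enteric neurons and glia had 12 of 22 (0.344), with Ret, Phox2a and Ednrb open and Sox10 without. Endothelium had 11 of 22 (0.180), mesothelium 8 of 13 (0.803) and enteroendocrine cells 16 of 22 (0.711), the last with the somatostatin gene Sst and the histidine decarboxylase gene Hdc open and the gastrin gene Gast without. Forestomach squamous epithelium had 12 of 22 (0.344), with the basal keratins Krt5 and Krt14 open and Trp63 without. Intestinal epithelium had 12 of 22 (0.344), with Vil1 and Lgr5 open. Of the intestinal regulators, Cdx1 had a promoter peak in replicate 1 only and Cdx2 in neither replicate. With only the stronger 50% of peaks, the enteroendocrine (31.8%), intestinal (22.7%), enteric (31.8%), endothelial (27.3%) and mesothelial (23.1%) lists lay below other genes. Against random lists matched on promoter CpG content, an alternative chosen after seeing the data, mesenchyme (percentile 1.35) and enteric neurons and glia (0.990) lay in the lowest 2.5%. These percentiles are not adjusted for the number of lists.

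**Figure D2:**
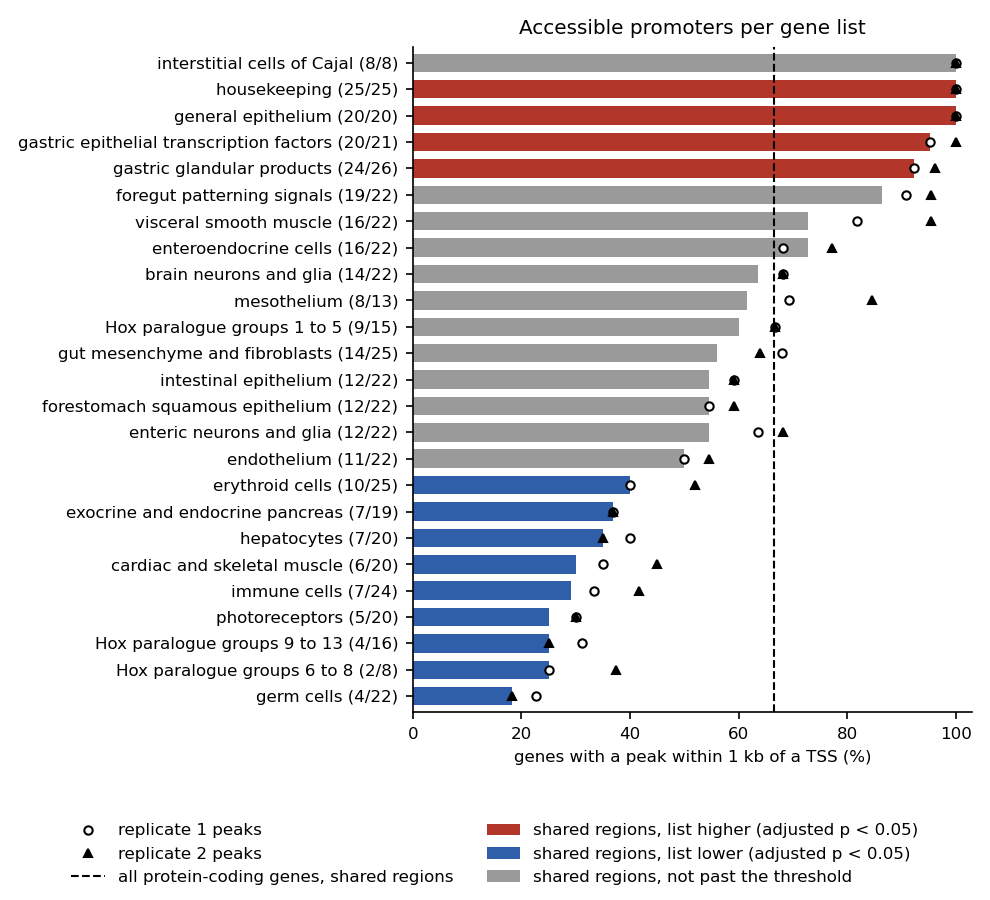
Percent of each list's genes with a peak within 1 kb of a transcription start (horizontal axis) for the 25 gene lists (vertical axis), with bars for shared regions (red higher, blue lower, grey not past the threshold), circles for replicate 1 and triangles for replicate 2. The dashed line marks the 66.4% of all protein-coding genes, and bars run from 18.2% for germ cells to 100% for general epithelium, interstitial cells of Cajal and housekeeping.

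Genes in most lists of other tissues, and in those of immune and erythroid cells, were less often open than other protein-coding genes. For most of these lists this did not hold against lists matched on promoter CpG content, given at the end of this paragraph. Only 4 of 22 germ cell genes had a shared promoter region (Gdf9, Tex14, Dmc1 and Dazl; adjusted p = 1.15e-04, BH, Fisher's exact test), and 5 of 20 photoreceptor genes did (Nrl, Rom1, Opn1sw, Cngb1 and Gnat1; 0.00151). Immune cells had 7 of 24 (0.00165), with Ptprc and Ikzf1 open and the T cell genes Cd3e and Cd4 without. Cardiac and skeletal muscle had 6 of 20 (0.00437), with the muscle regulators Myod1 and Myf5 without. Hepatocytes had 7 of 20 (0.0177), with Afp and Ttr open and Alb without, the pancreas list 7 of 19 (0.0257), with Pdx1 and Nkx6-1 open and Ins1 and Ptf1a without, and erythroid cells 10 of 25 (0.0210), with Tal1 and Epor open and Gata1 and Klf1 without. Brain neurons and glia had 14 of 22 (0.822). Olfactory receptor genes had a shared promoter region at 14 of 1134 (1.23%), and all chemoreceptor genes together at 19 of 1517 (1.25%). In replicate 2 alone the erythroid list (52%) and the muscle list (45%) no longer passed, and with the stronger 50% of peaks the pancreas list did not. Against lists matched on promoter CpG content the immune (percentile 9.03), muscle (5.19), pancreas (18.0), hepatocyte (40.8) and erythroid (50.7) lists were within chance. Germ cells (0) and photoreceptors (1.74) lay in the lowest 2.5%, without adjustment for the number of lists.

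Of the Hox genes, which pattern the body axis in the order of their position along each cluster, the posterior members were seldom open at their promoters. Of paralogue groups 1 to 5, 9 of 15 genes had a shared promoter region (adjusted p = 0.706, BH, Fisher's exact test), among them Hoxa4, Hoxa5, Hoxb1, Hoxb4 and Hoxc4. Of groups 6 to 8, only Hoxa7 and Hoxc6 did among 8 (0.0392). Of groups 9 to 13, 4 of 16 did (0.00353), namely Hoxa10, Hoxb9, Hoxc10 and Hoxc13. No HoxD gene of the lists had one, although 7 shared regions lay in or within 10 kb of that cluster (mm10 chromosome 2, 74668310 to 74765142). The HoxA cluster held 10, the HoxB cluster 13 and the HoxC cluster 6. Against lists matched on promoter CpG content, groups 1 to 5 lay at percentile 1.63 and both other lists at 0. With a 2.5 kb promoter window groups 6 to 8 stood at 75%, above the share of other genes, and in replicate 2 alone (37.5%) their difference was not past the threshold. The difference between the 3 Hox lists was not tested.

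**Figure D3:**
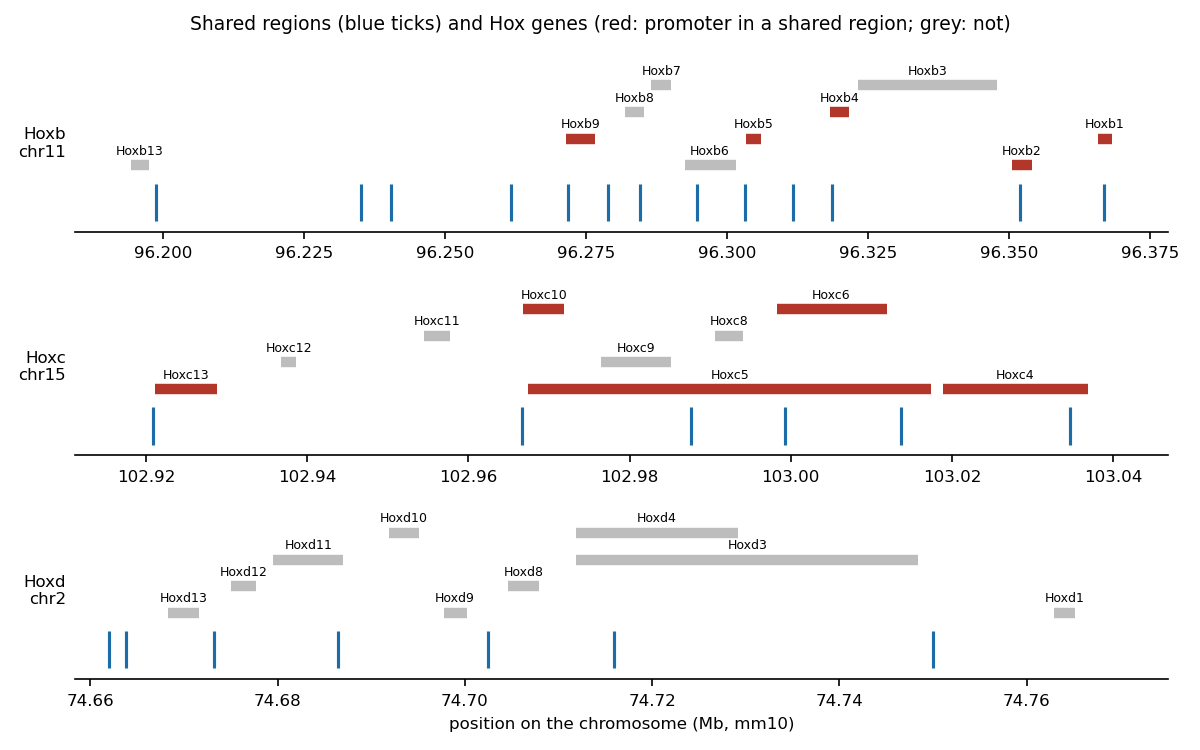
The HoxB, HoxC and HoxD clusters along their chromosomes (horizontal axis, position in Mb, mm10), with shared regions as blue ticks and genes as bars, red where a shared region lay within 1 kb of a transcription start and grey where none did. The HoxD genes are all grey beside 7 shared regions, and the HoxB and HoxC clusters hold 13 and 6 regions.

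Gastric regulators also stood out by the number of accessible regions around them. Foxa1, a pioneer factor of endoderm, had 22 shared regions within its gene body and 10 kb on either side (gene at mm10 chromosome 12, 57540628 to 57546916), Grhl2, a regulator of epithelial junctions, had 18 (chromosome 15, 37233036 to 37363569) and Creb3l1 16 (chromosome 2, 91982328 to 92024502). The median over the 21 gastric transcription factors was 8, against 4 in random lists of genes matched on locus length. General epithelium had a median of 7.5 against 3, with 19 regions at Cdh1 (chromosome 8, 106603351 to 106670246) and 13 at Krt19 and at Prss8, and housekeeping genes had 7 against 3. Glandular products had 5.5 against 4, with 31 regions at the potassium channel gene Kcnq1 (chromosome 7, 143106362 to 143427042), 12 at Tff1 and 11 at Capn9. In the smooth muscle list Sorbs2 had 22 regions and Synpo2 18, and its median was 7 against 5. Among foregut signals, also at 7 against 5, Fgfr2 had 212 over an annotated locus of 2981 kb and Fgf9 had 18. The count for Fgfr2 takes in the regions of any other genes within that span. Hepatocytes had 1.5 against 3.5, with 9 regions at Trf, and germ cells 2 against 4, with 22 at Tex14.

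In this comparison of loci, 4 lists ranked in the highest 2.5% of 10000 random lists and 2 in the lowest 2.5%, with ties ranked at their middle and no adjustment for the number of lists. General epithelium and housekeeping were at percentile 100, gastric transcription factors at 99.955 and glandular products at 98.2, and hepatocytes were at 2.34 and germ cells at 2.27. The medians of glandular products, hepatocytes and germ cells equalled the limits of the central 95% of random lists (5.5, 1.5 and 2), so these 3 calls rest on how ties are ranked, and mesothelium, also on its limit of 2, was not called. The call for gastric transcription factors ended at 97.1 with 50 kb on either side, and that for housekeeping at 94.6 without promoter regions. Glandular products fell to percentile 39.5 over gene bodies alone and were within chance in replicate 1 (97.02) and replicate 2 (87.8) taken alone, with 50 kb on either side (91.7), and with lists matched also on promoter regions (84.0). The hepatocyte call ended in replicate 1 alone (2.84) and under 5 other settings, at 9.29 to 43.3, and germ cells moved to 81.3 with lists matched also on promoter regions and its call ended under 5 other settings, at 4.25 to 27.0. The other 19 lists lay within chance, from percentile 3.64 for mesothelium to 94.7 for foregut signals and 94.2 for smooth muscle. Foregut signals passed in replicate 1 alone (99.2), with the stronger 50% of peaks (98.6) and with the mean over the list (99.7). That mean includes the 212 regions of Fgfr2, against 18 at the next member, Fgf9, and it was not computed without Fgfr2. Forestomach squamous epithelium, at 69.2, reached 99.8 without promoter regions, with Krt15, Sfn and Pkp1 holding 6, 8 and 6 regions in all. Smooth muscle reached 97.8 and enteroendocrine cells fell to 0.905 with lists matched also on promoter regions, enteric neurons and glia stood at 0.105 with 50 kb on either side, and mesothelium at 0.605 with the stronger 50% of peaks.

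Outside the lists, the protein-coding genes with the most shared regions included very long ones. Gm20388 had 451 regions over a locus of 4455 kb (chromosome 8, 119910841 to 124345722), and Gm37240 had 88. The locus of Gm20388 contains other genes, among them Gse1, and so counts their regions too. The phosphodiesterase gene Pde4d had 81, the transcription factor gene Mecom 75, Camta1 69, the Notch coactivator gene Maml3 59, Kalrn 54, Slc39a11 53, and Gse1 and Sgms1 50 each. The median protein-coding locus held 4, and 3961 loci held none.

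Binding sites of many factors were more frequent in shared regions than beside them. Those named in this paragraph as rarer were not set apart from windows matched on GC content. The site of CTCF, which organises chromatin loops, was in 5.30% of shared regions and 0.0536% of windows 1 kb away, an odds ratio of 104 (95% interval 85.1 to 127). The site of HNF1, an endodermal factor, had an odds ratio of 12.7 (7.99 to 20.1), that of GRHL, the Grainyhead-like epithelial factors, 7.65 (5.63 to 10.4), that of HNF4 4.94 (4.40 to 5.55) and that of AP-1 4.23 (4.09 to 4.38). Against windows matched on GC content HNF1 rose to 19.7 (3.94 to 98.3), but with 1 match in 20957 windows that interval overlapped the one of its reversed string (0.146 to 5.08) and the call was lost. On the same windows GRHL fell to 3.25 (1.87 to 5.62) and kept its call, while HNF4 and AP-1 stood at 5.02 and 4.35. FOXA sites were in 4.77% of regions against 2.34% (odds ratio 2.09, 2.00 to 2.18) and GATA sites in 9.75% against 6.78% (1.48, 1.44 to 1.52). In regions away from promoters the odds ratios were 135 for CTCF, 6.33 for HNF4, 5.22 for AP-1, 2.53 for FOXA and 1.84 for GATA. At promoters they were 36.8, 2.21, 2.13, 1.15 and 0.733. ETS, CREB and NFY sites, typical of broadly used promoters, had 15.3, 17.9 and 5.47 at promoters and 2.05, 4.29 and 1.36 elsewhere. Homeodomain strings were rarer in shared regions than beside them, with odds ratios of 0.536 for TAATTA and 0.467 for the PHOX2 site, and these strings read backwards were as rare, at 0.584 and 0.456. Against windows matched on GC content TAATTA stood at 1.10 (0.998 to 1.21) and the PHOX2 site at 1.03 (0.692 to 1.54), so neither was rarer there. The site of HOX groups 9 to 13 stood at 0.682, and its backward string at 1.25, and the SOX site at 0.846, with 1.04 backwards. Matched on GC content, the HOX site was at 0.925 (0.722 to 1.18) and the SOX site at 1.02 (0.936 to 1.11). The SRF site of muscle genes, the CArG box, did not differ from the windows 1 kb away, at 0.965 (0.889 to 1.05). Against windows matched on GC content it reached 1.31 (1.09 to 1.57), but that interval overlapped the one of its reversed string (0.893 to 1.31).

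Of 38 motifs, 20 were above the interval of their own string read backwards and past the threshold of Fisher's exact test after BH adjustment. Besides those named they were NFI (9.15), KLF CACC (5.43), the ERG core (2.22), IRF (2.09), the E-box CACGTG (1.98), TEAD (1.43), TAL1-GATA1 (1.42), MEF2 (1.33), RUNX (1.13) and MEIS (1.10). With background windows matched on GC content, HNF1 (19.7), NFI (7.27), IRF (2.51), TAL1-GATA1 (1.56) and MEIS (0.957) no longer passed, MEIS by Fisher's exact test and the others only because their intervals overlapped those of their reversed strings, and NFI (10.4) also did not with windows of 100 bp. C/EBP (4.45) did not pass, but did in each replicate alone and with windows of 100 bp. Over all shared regions NRF1 (18.2) passed under 1 alternative, GC-matched windows, and RFX (3.10) with those and in replicate 1 alone. Taken by class, NRF1 passed at promoters (38.1), and C/EBP (3.73) and the E-box CAGCTG (1.68) passed in distal regions. Motifs called over all regions that did not pass at promoters were GATA (0.733), TEAD (0.906), MEF2 (0.745), RUNX (0.643), TAL1-GATA1 (0.795), KLF CACC (4.76) and NFI (3.58). The difference between promoters and other regions was not tested, and shared regions had 52.3% GC against 45.2% beside them.

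**Figure D4:**
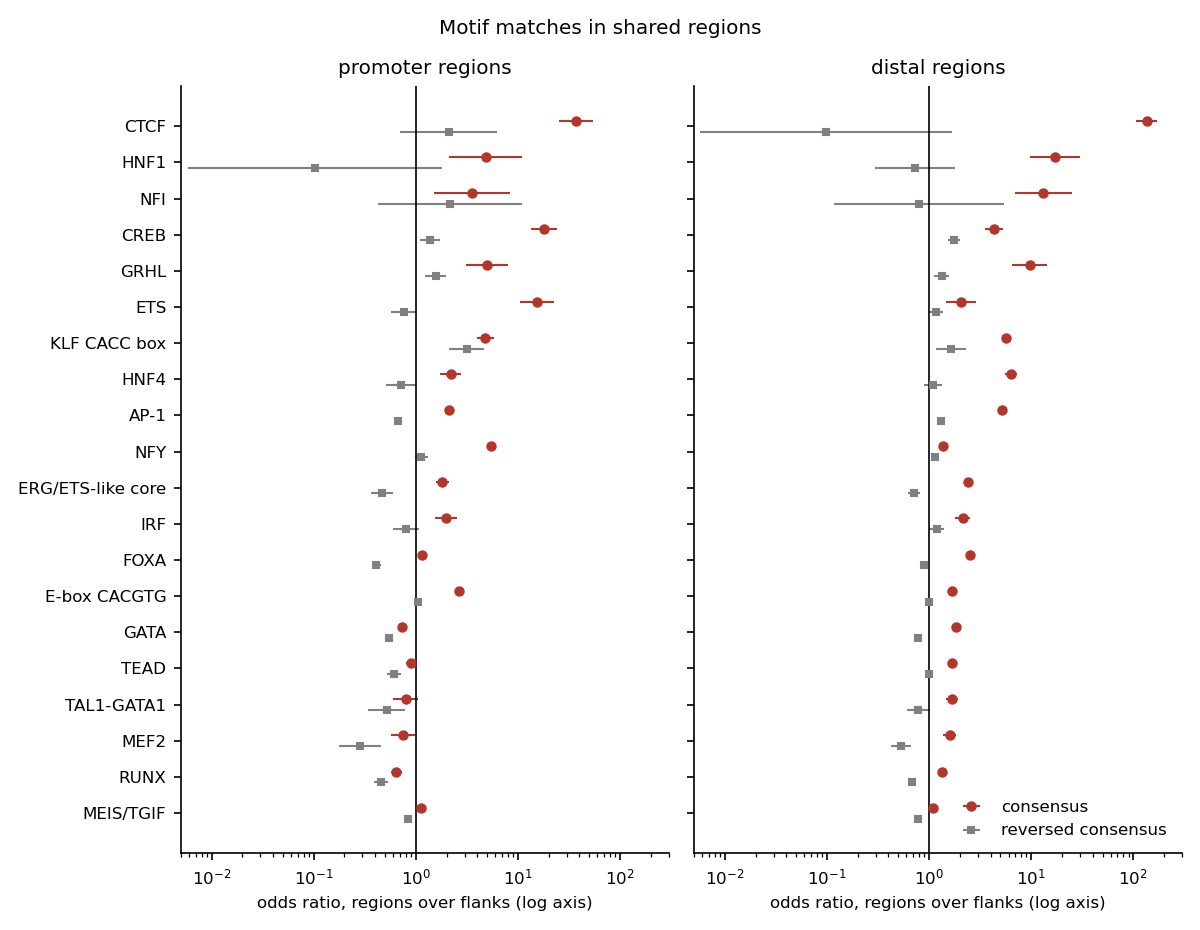
Odds ratio of a motif match in shared regions against windows 1 kb away (horizontal, log axis) for the 20 motifs above their reversed string over all shared regions (vertical axis), at promoters on the left and in distal regions on the right, with 95% intervals. Red points are the motif and grey squares its reversed string, with CTCF at 36.8 at promoters and 135 in distal regions and ETS at 15.3 and 2.05.

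By its share of all peaks, no list set the replicates apart. Over all protein-coding loci 52.7% of peaks came from replicate 2, and the exact binomial interval of each of the 25 lists included that share. It was 51.5% (47.0 to 55.9) for gastric transcription factors, 53.6% (49.2 to 57.9) for smooth muscle, 50.4% (44.1 to 56.7) for immune cells and 47.3% (37.7 to 57.02) for hepatocytes. Most peaks were found in both replicates and count on both sides, so a list that differed only in unshared peaks could be missed. Unshared peaks were not compared by list. Some single loci differed more. Sp9 had 3 peaks in replicate 1 and 29 in replicate 2 (gene at mm10 chromosome 2, 73271925 to 73284706), and its neighbour Cir1, whose locus overlaps that of Sp9, had 8 and 28. Gm20388 had 580 and 672, a difference that is small beside the number of peaks in its locus of 4455 kb. More were found in replicate 1 at Filip1l (41 and 23), Cmss1 (46 and 29), whose locus contains that of Filip1l and so counts the same peaks, Mid1 (74 and 61), Lrmda (68 and 55), Prdm16 (67 and 54), Casz1 (55 and 41) and Myo10 (42 and 27). These were the 10 genes with the largest absolute differences in number of peaks after scaling by the total, a ranking that favours loci with many peaks. With 1 library on each side they carry no test.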

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

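Of the tests below, those of the stronger 50% of peaks and of repeated sequence were chosen only after the result was seen.

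Peaks outside the autosomes, X and Y were a signal in data that no comparison above used. Replicate 1 had 18 peaks on the mitochondrial chromosome and 262 on unlocalized and unplaced scaffolds, and replicate 2 had 17 and 382.

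Peaks found in a single replicate numbered 31179 in replicate 1 and 44728 in replicate 2, with a median signal of 27 against 50 for shared peaks in replicate 1 and 38 against 62 in replicate 2. The test written beforehand, that a peak threshold splits weak sites, would have counted against that explanation with under 20% of them in a hotspot of the other replicate, and that bound was met at 12.97% for replicate 1 and 10.7% for replicate 2. The bound was ill chosen, which was recognised only after the values were seen: 0 of 128245 hotspots in replicate 1 and 0 of 138504 in replicate 2 lack a peak of their own replicate, so a site with no called peak near it lies in no hotspot, whatever its signal. Of the stronger 50% of peaks, 96.0% in replicate 1 and 92.0% in replicate 2 overlapped the other list, but these values restate the sharing by signal that prompted the test, so they decide nothing further. Whether a threshold, a difference in depth or in tissue separates the weak sites cannot be told apart without read counts, and no biological explanation was tested.

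The 10 windows of 10 kb with the most peaks over both lists stood far above the median of 2 among the 87833 windows with any, and the last of them, at Adamts18, held 17 peaks in replicate 1 and 16 in replicate 2, weak ones with a median signal of 12 and 14, against 44 and 52 over all peaks. The 2 windows at Mid1 (mm10 chromosome X, 169970001 to 169990000) held 25 and 19 peaks in replicates 1 and 2, and 22 in each, and at least 58.2% of the 32-base words in their peaks occur elsewhere in the assembly, against a mean of 4.25% in 2000 random shared regions, so reads of other copies may add to them. Where in the assembly those copies lie was not recorded, so the kind of repeat is not known here. In the other 8 windows, at Trpm8, Fgf9, Foxa1, Frmd8 and Neat1, the Ugt1a genes, Tnrc18, Zfp503 and Adamts18, the highest share was 0.420%, which argues against repeated sequence there. A first test of the median over all 10 windows gave 0.119%, and the Mid1 windows were separated after the share of each window was seen. Copies missing from the assembly stay open, and no biological explanation was tested.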

How the results depend on the processing

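With 1 group no paired analysis was possible, and the unknown read depth limits which weak sites each list holds. With the stronger 50% of peaks the shared regions numbered 60884, and 88.0% of replicate 1 and 80.2% of replicate 2 peaks were shared. These shares were 73.3 and 66.8% with an overlap of at least 50% of each peak, 74.3 and 74.0% with lists of equal length, and 79.3 and 72.3% for hotspots. Promoter, exon, intron and intergenic shares were 18.6, 6.23, 43.4 and 31.7% with a 250 bp promoter window, 41.7, 2.37, 29.6 and 26.3% with 2.5 kb, and 25.4, 2.71, 35.2 and 36.7% with protein-coding transcripts only. These move by construction with the window and the annotation. In each replicate alone they spanned 29.2 to 30.1, 3.70 to 3.77, 36.6 to 36.7 and 29.5 to 30.3%. Lists with more regions per locus than random lists, 4 as reported, were 2 with 50 kb on either side. Lists with fewer, 2 as reported, were 0 with gene bodies alone, 1 with 50 kb on either side, 0 with promoter regions left out, 1 with the stronger 50% of peaks, 1 with matching also on open promoters, 1 with the mean and 1 to 2 in each replicate alone. Reversed results were the promoter share of enteroendocrine cells (31.8% with the stronger 50% of peaks), that of Hox groups 6 to 8 (75% with the 2.5 kb window), the locus percentile of glandular products (39.5 with gene bodies alone) and that of germ cells (81.3 with matching on open promoters). Their cause was not tested. Of the comparisons of single lists and motifs with their alternatives, promoter shares kept their call in 177, gained one in 11, lost it in 10 and reversed in 2. Locus percentiles kept it in 173, gained one in 8, lost it in 17 and reversed in 2. Motifs kept it in 178, gained one in 6 and lost it in 6. The counts of lists with higher and with lower promoter shares stayed within 1.5 times the reported 4 and 9 under every alternative run, as did the count of motifs. The lists behind these counts changed, however. Against lists matched on promoter CpG content 5 promoter shares lost their call and 3 gained one. With the stronger 50% of peaks 2 lost it, 4 gained one and 1 reversed.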

Other observations

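Of the tests below, the 4 relations of motifs to lists were written before the data were examined, and the scan over all pairs, the omission of single genes and the listing of single windows were chosen after the results were seen.

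A few accessible regions at smooth muscle genes carried the site of SRF, the factor that drives contractile genes. Of 129 shared regions away from promoters in smooth muscle loci, 9 held a CArG box (6.98%), against 0.865% of the other distal regions. They lay in introns of Lmod1 (mm10 chromosome 1, 135347856 to 135348025 and 135359116 to 135359285), Pgm5 (chromosome 19, 24770496 to 24770665), Jph2 (chromosome 2, 163370276 to 163370445), Synpo2 (chromosome 3, 123204756 to 123204925), Tpm1 (chromosome 9, 67040916 to 67041105) and Flna (chromosome X, 74244736 to 74244925 and 74248676 to 74248845), and in an exon of Smtn (chromosome 11, 3535736 to 3535885). The matches included CCTTTTAAGG at Synpo2, CCATATAAGG at Smtn and CCTTATATGG at Tpm1. Over all shared regions the box had an odds ratio of 0.965 against windows 1 kb away. Against windows matched on GC content it had 1.31, with an interval that overlapped that of its reversed string. The regions with a match are named because they are few, after their values were seen.

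The relation of motifs to lists was predicted for 4 pairs, and 1 was found. For CArG boxes in smooth muscle loci the odds ratio was 9.03 (95% interval 4.64 to 17.6, BH adjusted p = 9.23e-06, Fisher's exact test). Leaving out each gene in turn gave at least 7.19 (without Flna). The reversed string, matched in 1 of 129 regions, gave 1.59 (0.318 to 7.99). The 2 intervals overlap, so the rule used above to call motifs was not met, and SRF sites at these genes remain a hypothesis. For GATA, FOXA or HNF4 sites in gastric epithelial loci it was 0.764 (0.532 to 1.10, with 34 of 237 regions, adjusted p = 0.301, Fisher's exact test), for ETS sites in endothelial loci 1.13 (0.224 to 5.69), where 1 of 79 regions had a match and the added 0.5 lifts the ratio above 1, and for p53 family or AP-1 sites in forestomach loci 1.19 (0.574 to 2.47, with 8 of 55). The bound written against these 3, an interval that includes 1, was met. For the gastric loci the predicted enrichment was not found, with an interval that reached 1.10. That interval counts regions of the same locus as independent, so it sets no firm bound on what remains. The endothelial and forestomach intervals are too wide to decide. A scan of 950 pairs of lists and motifs found 1 past the threshold, the same pair (adjusted p = 0.00219, BH, Fisher's exact test). Base composition was weighed by the reversed string alone, and the design has no groups that would test a biological explanation.

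Windows of 10 kb that differed most between replicates were listed after their values were seen, and 1 library on each side allows no test. Replicate 2 had more peaks at Sp9 (1 in replicate 1 and 21 in replicate 2; mm10 chromosome 2, 73270001 to 73280000), beside Cyp3a16 (0 and 13, these with a median signal of 12), at Foxc1 (2 and 15), at Npr3 (1 and 13) and near Calm2 (0 and 11). Replicate 1 had more, besides a window at Mid1 (25 and 19), at the metallothionein genes Mt1 and Mt2 (12 and 2; chromosome 8, 94170001 to 94180000), Meis1 (10 and 2), Tmem63a (13 and 6) and Szrd1 (13 and 6).

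On the sex chromosomes, promoters of Xist had 2 peaks in each replicate, and those of the Y-linked genes Uty, Kdm5d, Eif2s3y and Ddx3y had 2 to 4 in each. Sry, Zfy1 and Usp9y had none in either. The X chromosome held 3274 and 3500 peaks and the Y chromosome 52 and 62.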
